A study of Mus musculus with 6 samples.

How the data were processed

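The series holds 6 RNA-seq libraries from C2C12 cells grown in medium with 10% fetal bovine serum, 3 transfected with a random control siRNA and 3 with an siRNA against Cox7a2l. Per the labels' protocols, 2 µg of total RNA was depleted of ribosomal RNA, fragmented, reverse transcribed with random primers, and made into dUTP-stranded libraries sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name Trim Galore 0.6.4, Salmon 0.13.1, DESeq2 1.30.1 and the genome build mm39, without saying which step each did. The annotation release and the step from transcripts to genes are not given in the sources used here.

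The authors deposited estimated counts per gene, which were not scaled to depth and were not whole numbers in 12.5% to 14.3% of values. They also deposited TPM values, scaled to transcript length and to the same sum in each library. A result table deposited by the authors holds, per its file headers, scaled counts per library, their mean, log2 fold changes with standard errors, and p-values with adjusted p-values. Its scaled counts, a normalised signal, equal the deposited counts rounded to whole numbers and divided by 1 size factor per library (0.647 to 1.24). Each log2 value of that table was compared with DESeq2 models refitted here. A model with a term for replicate 3 against replicates 1 and 2 gave the authors' deposited log2 fold changes to within 1.3e-09 and the same 808 calls, while the model of group alone called 27 genes and the model with replicate number 495.

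Gene symbols were joined by gene identifier without its version, since only 35 versioned identifiers match the reference used here (GENCODE M21 on GRCm38), and 97.6% of the 52740 gene rows received one. No coordinates are given, because this reference is another build than mm39. One gene row without a symbol in the reference took 5.81% to 11.1% of the counts and 36.9% to 53.6% of TPM in each library, so TPM values of the other genes depend on it. Library totals ran from 9890218 to 17077826 estimated counts, with the smallest in Cox7a2l siRNA replicate 3. The precision of low genes is lowest there.

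Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter by group (15022 genes kept), robust quasi-likelihood fits (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. Log2 values of single pairs come from log2 CPM with edgeR's default prior count of 2, which draws the values of low genes towards 0. Log2 differences of replicate 3 from the mean log of replicates 1 and 2 had 0.5 CPM added, with the same effect. The standard error of a log2 fold change is its size over the root of the F statistic. The fit of group alone, without the replicate number, was fixed as the main design before the data were examined, with the replicate block, other scalings, filters and tools, and leaving out each library, as alternatives. The design foresaw counts, and the files hold estimated counts, hence the rounding. Because the labels give both groups replicate numbers 1 to 3, pairing was checked on deviations from the group means across genes. Libraries of the same number correlated at 0.53, 0.45 and 0.67, against at most 0.44, 0.43 and -0.51 with another number. Each library thus correlated best with that of its own number in the other group, by a narrow margin for replicates 1 and 2. Deviations from a mean of 3 libraries sum to 0, so replicate 3, far from the others, makes replicates 1 and 2 correlate across numbers as well. The numbers were taken to pair the samples because each of the 3 correlations is above 0.1, a threshold that replicates 1 and 2 also pass across numbers. The pairing is clear only for replicate 3. No label says what a number shares.

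The 2 most similar libraries were control replicates 1 and 2. Over 5499 genes with whole counts and a mean of at least 50, a chi-square test with 1 degree of freedom had a median of 0.787, against 0.455 for counting noise alone, and 14.5% of genes had p under 0.05. Cox7a2l siRNA replicates 1 and 2 gave a median of 4.71, and pairs with replicate 3 gave 13.3 to 15.5. The control pair differed by more than counting noise and was kept as 2 samples.

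Of 46 gene lists fixed before the data were examined, 42 had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Named genes were Cox7a2l, up to 10 genes per direction with the largest change among those called (mean of at least 2 CPM, groups not overlapping, no unnamed gene models), up to 2 called members per direction of each list, and a fixed set (Myod1, Myog, Myh3, Mymk, Ckm, Cdkn1a, Mki67, Cox7a1, Cox7a2). Not every gene that the rule names is given in the text. The rule was written for the fit without the block, where it named only Cox7a2l. Its use on the fit with the replicate block was chosen after the data were seen, as were the term for replicate 3, the fits without both replicate 3 libraries, and the alternatives of the blocked fit. Gm6969 and the list members named only for their values in replicate 3 were also chosen after their values were seen.

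The alternatives used DESeq2 1.42.0, limma with voom, limma on log2(TPM + 1) and log2(TPM + 0.1), and glmTreat against a 1.2-fold change. On log2(TPM + 1) the median of all tested genes was -0.18, against 0.01 with TMM. The scripts were tested on simulated data drawn from the real means and library sizes with 200 of 14652 genes changed. The means, with the group effect removed, and the spread came from the fit with the replicate block. That block is thus favoured by construction, so the simulation does not show which design suits the data. Without the block 6% of 2-fold and 70% of 4-fold changes were recovered with 0 false calls, with the replicate block 82% and 100% with 9 false calls, and with the term for replicate 3 71% and 98% with 3. Of 200 random lists of unchanged simulated genes, 1% had a camera p under 0.05 with the block. Simulated genes were drawn independently of one another, so this share does not cover lists whose genes move together. The estimated correlation with the block was 0.69 for S phase and 0.86 for G2 and mitosis.

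Transcript length and GC content were taken from the longest transcript of each gene in the reference. For the shared sequence of Gm6969 and Cox7a2l, all words of 31 bases in their transcripts were compared.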

Results

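RNA was sequenced from C2C12 cells, a mouse myoblast line that can be driven to form contractile myotubes, after transfection with a random control siRNA or an siRNA against Cox7a2l. Cox7a2l encodes a protein of the inner mitochondrial membrane that joins respiratory complexes III and IV into supercomplexes. Each group held 3 libraries, prepared from ribosomal RNA-depleted total RNA with strand marking by dUTP. The series' title places the question in myoblast differentiation, and the design gives 1 comparison, Cox7a2l siRNA against control siRNA. Total estimated counts were 14896035, 14310241 and 17077826 in control replicates 1, 2 and 3, and 15095348, 14129822 and 9890218 in Cox7a2l siRNA replicates 1, 2 and 3. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

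Replicate 3 of both groups stood apart from replicates 1 and 2. The first principal component held 61.2% of the variance and separated the replicate 3 libraries from the other 4, and the second held 21.2%. Messages of the 13 protein genes of mitochondrial DNA took 2.78% of the counts in control replicate 3 and 1.61% in Cox7a2l siRNA replicate 3, against 0.589% to 0.616% in the other 4 libraries. Some muscle differentiation genes were also more abundant there. Myog, a transcription factor of early differentiation, had 2.90, 3.78 and 61.1 CPM in control replicates 1, 2 and 3 and 9.57, 1.33 and 159 CPM after Cox7a2l siRNA. Myh3, the embryonic myosin heavy chain, had 0.792, 1.31 and 21.9 CPM, and 2.98, 1.19 and 53.1 CPM. Others differed less, with 130.2, 127 and 134 CPM, and 118, 126 and 161 CPM, for Myod1, and 2.11, 2.96 and 4.41 CPM, and 1.33, 2.53 and 1.35 CPM, for Mef2c. These are single libraries against 2, with no test. Some signs of RNA composition moved with the groups as well, beside every gene group below. One gene row without a symbol took 6.59%, 6.25% and 5.81% of the counts in control replicates 1, 2 and 3 and 6.97%, 7.57% and 11.1% after Cox7a2l siRNA. Mitochondrial ribosomal RNA took 0.158%, 0.136% and 0.169% against 0.218%, 0.164% and 0.233%. Lars2, also listed for RNA quality and depletion, took 1.67%, 1.45% and 0.533% against 0.995%, 0.915% and 0.803%. It was thus lower after Cox7a2l siRNA in pairs 1 and 2 and higher in pair 3. Because replicate 3 stood apart, fold changes below come from the edgeR fit with the replicate number as a block, which compares libraries of the same number. Replicates 1 and 2 correlated with their own number only narrowly better than across numbers (0.53 and 0.45 against 0.44 and 0.43). Pairs 1 and 2 below are therefore uncertain as pairs. The term for replicate 3, given as an alternative, does not rest on them. The block does not remove signs of RNA composition that differ between the groups within a pair. For gene lists the result without the block stands beside them where the call differs. Leaving out 1 library without the block gives replicate 3 unequal weight in the groups. Changes in such fits can therefore come from the replicate 3 difference. Of the single genes named below as past the threshold, only Cox7a2l and Gm6969 also passed in the edgeR fit of the 6 libraries without the block, where the others had edgeR adjusted p from 0.311 (Itgb8 and Taldo1) to 0.918 (Actc1). DESeq2 without the block also called some of them, among them Npr3 (adjusted p = 1.3e-06), Taldo1 (1.5e-07), Itgb8 (1.8e-07), Plk3 (5.0e-04), Txnip (0.00152), Col6a2 (0.00366) and Ccnd1 (0.00601).

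**Figure D1:**
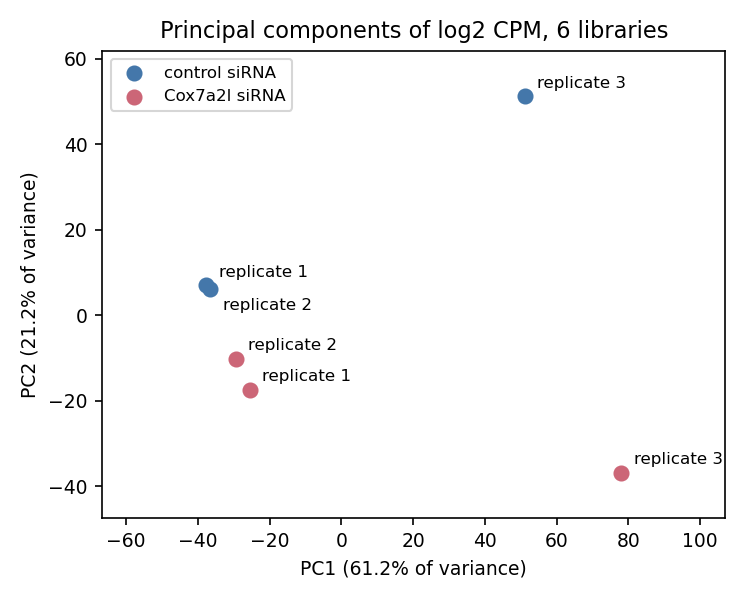
Principal components of TMM-scaled log2 CPM over 15022 genes, with each point 1 library, blue for control siRNA and red for Cox7a2l siRNA. The x axis (61.2% of the variance) parts both replicate 3 libraries from the others, and Cox7a2l siRNA libraries lie below the control library of the same number on the y axis (21.2%).

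Cox7a2l (ENSMUSG00000024248.15, chromosome 17) was lower in each library that received its siRNA. Its normalised count was 58.8 ± 0.759 CPM in the control group and 5.40 ± 1.62 CPM in the Cox7a2l siRNA group (SD, n = 3 each), 0.0923 times the control level. The log2 fold change was -3.43 with a standard error of 0.25 without the block (edgeR adjusted p = 0.0122) and -3.44 with a standard error of 0.19 with the replicate block (edgeR adjusted p = 1.9e-05). The 3 pairs gave -3.08, -3.30 and -3.98. Without the block the call held when Cox7a2l siRNA replicate 3 was left out (adjusted p = 0.00887) and was lost when any other library was. Leaving out control replicate 1, 2 or 3 gave adjusted p = 0.0816, 0.0962 and 0.103, and leaving out Cox7a2l siRNA replicate 1 or 2 gave adjusted p = 0.112 and 0.286, with the log2 fold change between -3.61 and -3.22 throughout. The only other gene past the threshold without the block was the processed pseudogene Gm6969, at 21.5 ± 4.50 CPM against 0.867 ± 0.175 CPM (SD, n = 3 each; log2 fold change -4.60, edgeR adjusted p = 0.00768). Its call was also lost without Cox7a2l siRNA replicate 1 or 2 (adjusted p = 0.112 and 0.228). Of the 31-base words in its transcript, 78.2% also occur in Cox7a2l transcripts, so its value is uncertain as a level of its own. The paralog Cox7a2, a subunit of complex IV, had a log2 fold change of -0.22 with a standard error of 0.15 and did not pass (edgeR adjusted p = 0.471). Cox7a1, the muscle paralog, was too low to be tested.

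**Figure D2:**
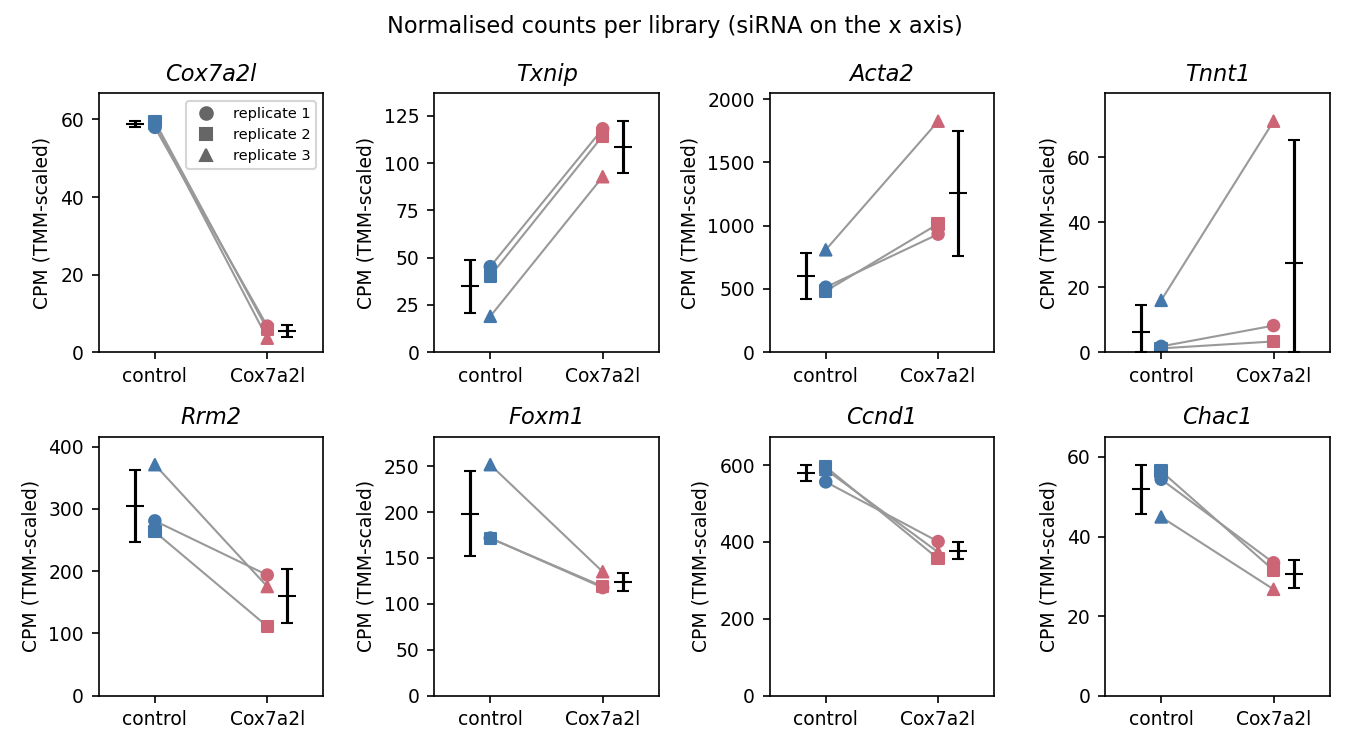
TMM-scaled CPM of 8 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3, lines joining libraries of the same number, and black bars for the mean and SD of the 3 libraries (bars are clipped at 0). Cox7a2l lay at 58.0 to 59.5 CPM in the control libraries and at 3.59 to 6.72 CPM after its siRNA, and Tnnt1 spread more between replicates than between groups.

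In the fit with the replicate block 109 of 15022 genes passed, 65 higher and 44 lower, with Cox7a2l and Gm6969 among those lower. Among those higher were Txnip, which binds thioredoxin and restrains glucose uptake (3.29 times the control level, log2 fold change 1.72, standard error 0.18, edgeR adjusted p = 0.0024), Npr3, the clearance receptor for natriuretic peptides (3.80 times), and Taldo1, transaldolase of the pentose phosphate pathway (2.41 times). Itgb8, an integrin chain, rose to 2.57 times, the matrix protein gene Hmcn1 to 3.17 times, the guidance ligand Sema3d to 2.33 times and Top1mt, the mitochondrial DNA topoisomerase, to 2.24 times. Plxdc2, Ctxn1 and Dnajc30 rose to 4.17, 3.34 and 2.46 times. Without the block the log2 fold change of Plxdc2 was 2.07, and 1.25 when Cox7a2l siRNA replicate 3 was left out. Among the genes that fell were Plk3, a stress-linked kinase (0.456 times, log2 fold change -1.13, standard error 0.16, edgeR adjusted p = 0.0117), Dock8 (0.425 times) and Lims2 of focal adhesions (0.426 times). Fyb2, Tigit, Siglecg, Ptprn and Sema4f fell to between 0.325 and 0.452 times. For these 18 genes the edgeR adjusted p lay between 0.0024 and 0.0419 with the block and between 0.311 and 0.754 without it. Each had its 3 Cox7a2l siRNA libraries on one side of its 3 control libraries, because the naming rule required it. That separation is therefore no further support, and other called genes, such as Tnnt1 and Dcn, had overlapping groups.

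The count depended on how the replicate 3 libraries were modelled. Without the block 2 genes passed, 0 higher and 2 lower, with 954 genes at an unadjusted p under 0.05, against 2661 with the replicate block. DESeq2 without the block called 40 genes, of which 33 were among the 109. A term that sets replicate 3 apart from replicates 1 and 2, chosen after the data were seen, gave 197 genes (118 higher, 79 lower), 99 of them among the 109. Within replicates 1 and 2 alone, 3 genes passed (Txnip besides Cox7a2l and Gm6969), with 1939 at an unadjusted p under 0.05, and the replicate 3 pair alone allows no test. With the replicate block and 1 pair left out, 373 genes passed without pair 1, 1210 without pair 2 and 51 without pair 3. The count also depended on tool, filter and scaling. With the block DESeq2 called 507 genes (232 higher, 275 lower), and edgeR without a filter called 1257 (568 higher, 689 lower). Scaling by library size alone gave 58 with the block (41 higher, 17 lower). Tested with limma on log2 TPM and the block, 12 passed (5 higher, 7 lower).

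Genes of DNA replication and mitosis were lower after Cox7a2l siRNA. Of 39 tested genes of S phase and replication, each had a negative log2 fold change, with a median of -0.60, and 38 were lower in all 3 pairs. Over all genes 2 of them fell, Rrm2, a subunit of ribonucleotide reductase (305 ± 57.8 to 160 ± 43.2 CPM, SD, n = 3 each; 0.517 times, edgeR adjusted p = 0.0231, and 0.0507 with the term for replicate 3), and Cdc45 of the replicative helicase (0.572 times, edgeR adjusted p = 0.0488), and 34 did when adjusted over the list alone. Of 40 tested genes of G2 and mitosis, each was likewise negative, with a median of -0.49, and 38 were lower in all 3 pairs. Over all genes Foxm1, a transcription factor for mitotic genes, fell to 0.635 times (edgeR adjusted p = 0.046), and 33 members did when adjusted over the list alone. Mki67, a marker of cycling cells, had a log2 fold change of -0.81 with a standard error of 0.22 and did not pass (edgeR adjusted p = 0.113). Of 22 histone genes expressed with replication, 0 passed over all genes and 14 fell when adjusted over the list alone, with a median of -0.38. Against all other genes the 3 lists were lower by camera with the replicate block (adjusted p = 1.0e-27, 1.7e-23 and 5.6e-09) and without it (adjusted p = 3.9e-25, 5.7e-25 and 1.9e-04). Each had adjusted p = 0.580 with an estimated correlation, with the block. Pair medians were -0.49, -0.36 and -1.02 for S phase and replication and -0.36, -0.28 and -1.0 for G2 and mitosis, in the order of pairs 1, 2 and 3. Without the block the histone call was lost when Cox7a2l siRNA replicate 3 was left out (median -0.09, adjusted p = 0.159).

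Among regulators of the cycle, Ccnd1 (cyclin D1) fell from 580 ± 20.9 to 377 ± 22.5 CPM (SD, n = 3 each; 0.649 times, edgeR adjusted p = 0.046). It was 1 of 18 tested genes of a list that mixes D-type cyclins with CDK inhibitors and genes of cell cycle exit. That list was not called with the block (median -0.09, camera adjusted p = 0.417). When adjusted over the list alone, 1 of its members rose and 3 fell. Cdkn1a, the CDK inhibitor p21, had a log2 fold change of 0.36 with a standard error of 0.19 (edgeR adjusted p = 0.356). Within replicates 1 and 2 alone this list was lower (median -0.21, camera adjusted p = 0.0233). It was also lower without the block when Cox7a2l siRNA replicate 3 was left out (median -0.24, adjusted p = 8.9e-04). That fit keeps replicate 3 in the control group only. The list was higher in replicate 3 of both groups (median log2 difference 0.27 and 0.65), so this call is no further support. As a mixed list, it does not show a fall of the CDK inhibitors as such.

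Contractile genes were higher. Of 29 tested sarcomere genes, 24 had a positive log2 fold change, with a median of 0.60, and 16 were higher in all 3 pairs. Of them 4 rose over all genes, 15 when adjusted over the list alone, with 0 lower in either. Tnnt1, the slow troponin T, rose to 4.09 times the control level (log2 fold change 2.03, standard error 0.20, edgeR adjusted p = 0.0023), and Actc1, the cardiac alpha-actin, to 2.94 times (edgeR adjusted p = 0.0263). With the term for replicate 3 in place of the block, Actc1 had adjusted p = 0.245. Myh3 had a log2 fold change of 1.14 with a standard error of 0.29 and did not pass (edgeR adjusted p = 0.0945). The sarcomere list was higher by camera with the block (adjusted p = 1.1e-11) and without it (adjusted p = 0.006), and had adjusted p = 0.580 with an estimated correlation. Its pair medians were 0.50, 0.13 and 0.75. Without the block the call was lost without control replicate 1 or 2 (adjusted p = 0.210 and 0.234), and the median turned to -0.58 without Cox7a2l siRNA replicate 3 (adjusted p = 0.185). There Tnnt1 and Actc1 had log2 fold changes of -0.15 and -1.86.

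Genes of excitation-contraction coupling and acetylcholine receptors were called higher with the block and not without it (20 tested, median 0.31, adjusted p = 0.00291 and 0.0694). They were called on TPM (median 0.01 against -0.18 for all genes, adjusted p = 0.0378). Without the block they were also called without control replicate 3 or Cox7a2l siRNA replicate 1 or 2 (adjusted p = 6.3e-04, 0.00952 and 3.9e-04). Each of these fits gives replicate 3 more weight in the Cox7a2l siRNA group. No further support follows, since these genes were higher in replicate 3 of both groups (median log2 difference 0.62 and 1.16). Their median turned negative, with no call, when Cox7a2l siRNA replicate 3 was left out. None of their members passed over all genes, and 5 rose when adjusted over the list alone. The call had adjusted p = 0.676 with an estimated correlation, and was lost without pair 3 (adjusted p = 0.0708). The regulators of the muscle lineage were not called. Of 16 tested myogenic regulatory factors 0 passed over all genes, while 1 rose and 1 fell when adjusted over the list alone (median 0.16, camera adjusted p = 0.489). Myod1 had a log2 fold change of 0.03 with a standard error of 0.13 (edgeR adjusted p = 0.921). Without the block its sign was negative on TPM and on library size alone, where the medians of all genes were -0.18 and -0.03. Myog had 0.90 with a standard error of 0.71 (edgeR adjusted p = 0.616), and its pairs gave 1.67, -1.41 and 1.38. The fusion factor Mymk had -0.04 with a standard error of 0.41 (edgeR adjusted p = 0.978), and of 18 tested myoblast fusion genes 0 passed under either adjustment (median -0.01, camera adjusted p = 0.787). Ckm, the muscle creatine kinase, was too low to be tested.

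Matrix and actin genes moved in both directions. Of 37 tested genes of extracellular matrix and TGF-beta response, 4 rose and 1 fell over all genes, and 17 rose and 3 fell when adjusted over the list alone. Acta2, the smooth muscle alpha-actin, rose from 602 ± 180 to 1258 ± 494 CPM (SD, n = 3 each; 2.05 times, log2 fold change 1.04, standard error 0.12, edgeR adjusted p = 0.0056). Col6a2, a collagen VI chain, rose to 1.86 times (edgeR adjusted p = 0.0158), and Dcn, the proteoglycan decorin, to 3.29 times (edgeR adjusted p = 0.0419). Without the block the log2 fold change of Dcn was 1.85, and it was 0.33 when Cox7a2l siRNA replicate 3 was left out and 3.16 when control replicate 3 was. The list was higher with the block (median 0.24, camera adjusted p = 1.2e-04) and without it (adjusted p = 0.0332), and had adjusted p = 0.580 with an estimated correlation. It was not called with the block without pair 2 (adjusted p = 0.0616), nor without the block when control replicate 1 or 2 or Cox7a2l siRNA replicate 2 or 3 was left out (adjusted p = 0.210, 0.163, 0.236 and 0.159). Fibroblast markers, which include Dcn, were higher with the block and not without it (7 tested, median 0.26, adjusted p = 0.0469 and 0.110), with Dcn the 1 member that rose under either adjustment. That call had adjusted p = 0.580 with an estimated correlation, and was lost without pair 1 or pair 2 (adjusted p = 0.112 and 0.0589) and with the term for replicate 3 (adjusted p = 0.0654). Within replicates 1 and 2 alone the list was called (adjusted p = 0.0233). Its median on TPM was -0.05, against -0.18 for all genes.

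Over the 6 libraries and with the default filter, signalling lists were called higher with the replicate block, not in the fit of group alone, and again with the term for replicate 3 (adjusted p = 0.00442 for Notch and Id genes, 0.00615 for the IGF list and 0.0429 for atrophy genes). Heyl, a target of Notch, rose to 3.38 times (edgeR adjusted p = 0.0058), and 3 of 18 tested Notch and Id genes rose when adjusted over the list alone (median 0.20, camera adjusted p = 0.00171, against 0.0753 without the block). Without the block and Cox7a2l siRNA replicate 3, Heyl had a log2 fold change of -1.05. Of 24 tested genes of IGF, insulin and growth factor signalling, the HGF receptor gene Met fell to 0.606 times (edgeR adjusted p = 0.0388), while 5 rose and 1 fell when adjusted over the list alone (median 0.18, camera adjusted p = 0.00359, against 0.0693 without the block). Both lists had adjusted p = 0.580 with an estimated correlation. Fbxo32, the atrophy ubiquitin ligase atrogin-1, rose to 1.96 times (edgeR adjusted p = 0.0378) as the only member past either adjustment of 16 tested genes of muscle atrophy and proteolysis (median 0.20, camera adjusted p = 0.0388, against 0.0601 without the block). That list had adjusted p = 0.676 with an estimated correlation and was not called without pair 3 (adjusted p = 0.154). Without the block, Notch and Id genes were called over genes with a mean of at least 2 CPM (adjusted p = 0.0303) and within replicates 1 and 2 (0.0465), and muscle atrophy genes over genes with that mean (0.0421). The IGF list was called within replicates 1 and 2 (0.00551) and without control replicate 3 (0.00269) or Cox7a2l siRNA replicate 1 (0.00715). The Notch list was called without Cox7a2l siRNA replicate 1 (0.0162), and the atrophy list without control replicate 2 (0.0362). Fits that leave out 1 library weigh replicate 3 unequally between the groups. The IGF list was higher in replicate 3 of both groups (median log2 difference 0.27 and 0.47), so its calls in those fits are no further support. On TPM, where the median of all genes was -0.18, the medians of these 3 lists were -0.06, -0.08 and -0.01.

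Genes of the integrated stress response were lower. Of 34 tested, 29 had a negative log2 fold change (median -0.35), 22 were lower in all 3 pairs, 3 fell over all genes and 12 when adjusted over the list alone, with 0 higher in either. Chac1, a glutathione-degrading enzyme induced by ATF4, fell from 51.9 ± 6.14 to 30.6 ± 3.44 CPM (SD, n = 3 each; 0.589 times, edgeR adjusted p = 0.037), and Psat1 of serine synthesis to 0.571 times (edgeR adjusted p = 0.04). The list was lower by camera with the block (adjusted p = 5.6e-09) and without it (adjusted p = 1.7e-06), and had adjusted p = 0.580 with an estimated correlation. Targets of hypoxia signalling were also lower (25 tested, median -0.28, 0 past over all genes, 1 lower when adjusted over the list alone). They had camera adjusted p = 9.1e-04 with the block and 0.0041 without it, and adjusted p = 0.580 with an estimated correlation. Genes of cytosolic ribosomal proteins were lower by little (53 tested, median -0.15, 0 past over all genes, 1 lower when adjusted over the list alone). They had camera adjusted p = 7.4e-04 with the block and 0.0102 without it, and adjusted p = 0.656 with an estimated correlation. Without the block and Cox7a2l siRNA replicate 3, the hypoxia and ribosomal lists had adjusted p = 0.159 and 0.201, and the ribosomal list had 0.0763 without control replicate 2.

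Interferon-stimulated genes were higher (23 tested, median 0.39), with 0 past over all genes and 1 higher when adjusted over the list alone. Their camera adjusted p was 0.00728 with the block and 0.006 without it, and adjusted p = 0.580 with an estimated correlation. On TPM their median was -0.03, where the median of all genes was -0.18. Genes of autophagy and lysosome were higher (30 tested, median 0.22, 0 past under either adjustment), with camera adjusted p = 0.0111 with the block and 0.00822 without it, and adjusted p = 0.762 with an estimated correlation. That call was lost with the block without pair 3 (adjusted p = 0.176) and without the block when Cox7a2l siRNA replicate 3 was left out (adjusted p = 0.159) or both replicate 3 libraries were (median 0.11, adjusted p = 0.162). On TPM it was also lost (median -0.09, adjusted p = 0.193).

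For the respiratory chain itself, the shift was small. Of 36 tested nuclear genes of complex I, 34 had a positive log2 fold change, with a median of 0.19, and 14 were higher in all 3 pairs. None passed over all genes, and 1 rose when adjusted over the list alone. The list was higher by camera with the block (adjusted p = 9.1e-04) and without it (adjusted p = 0.00355), and had adjusted p = 0.762 with an estimated correlation. Pair medians were 0.12, 0.03 and 0.41. Without the block the call was lost when Cox7a2l siRNA replicate 3 was left out (adjusted p = 0.159), within replicates 1 and 2 (adjusted p = 0.0522), and on TPM (adjusted p = 0.155), where the median turned to -0.08 against -0.18 for all genes. Nuclear genes of complexes III and IV and of ATP synthase were not called with the block (9, 11 and 15 tested, medians 0.05, 0.16 and 0.06, camera adjusted p = 0.301, 0.179 and 0.301), and 0 of their members passed under either adjustment. Complex IV was called with the block and pair 2 left out (median 0.20, camera adjusted p = 0.033). The 13 messages of mitochondrial DNA had pair medians of 0.14, 0.00 and -0.66, and 0 passed under either adjustment (camera adjusted p = 0.417). Without the block that list was called lower without Cox7a2l siRNA replicate 3 (median -1.75, adjusted p = 0.00162) and higher without control replicate 3 (median 1.66, adjusted p = 8.6e-04). Each of these fits keeps replicate 3 in 1 group only. The messages were higher in replicate 3 of both groups (median log2 difference 3.36 and 2.78), so these calls do not measure the siRNA. With the block and pair 1 left out the list was called lower (median -0.26, camera adjusted p = 0.0193).

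The other metabolic and mitochondrial lists were not called in either fit over the 6 libraries. With the block, camera gave adjusted p = 0.252 for assembly factors (35 tested, median 0.08), 0.424 for biogenesis and mitochondrial DNA maintenance (20, 0.07), 0.452 for fusion and fission (16, 0.09), 0.414 for the TCA cycle (26, -0.05), and 0.0909 for glycolysis and lactate (21, -0.09). Glycolysis was called lower within replicates 1 and 2 (adjusted p = 0.0444) and without the block when control replicate 3 was left out (adjusted p = 0.0361). The latter fit keeps replicate 3 in the Cox7a2l siRNA group only. Glycolysis was lower in replicate 3 of both groups (median log2 difference -0.23 and -0.35), so that call is no further support. Fatty acid oxidation had adjusted p = 0.527 (21, 0.06), mitochondrial chaperones and proteases 0.547 (13, -0.03), and mitochondrial ribosomal proteins 0.248 (61, 0.07), which were called higher with the block and pair 2 left out (median 0.17, adjusted p = 0.033). Cholesterol synthesis had 0.0823 (25, 0.10) and was called higher within replicates 1 and 2 (adjusted p = 0.00169), where its pair 2 median was 0.42 against 0.01 in pair 1. It was also called without the block when control replicate 3 or Cox7a2l siRNA replicate 1 was left out (adjusted p = 0.00269 and 0.00643), and with the block without pair 1 or pair 3 (0.0296 and 0.0014). Those fits without the block weigh replicate 3 more in the Cox7a2l siRNA group. The list was higher in replicate 3 of both groups (median log2 difference 0.27 and 0.21). Top1mt was the only member of these lists past the threshold over all genes. Adjusted over the list alone, Top1mt was the 1 gene of biogenesis, 1 gene rose and 1 fell of the TCA cycle, 1 fell of glycolysis, and 0 passed in the others.

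The remaining stress, signalling and marker lists were not called with the block either. Camera gave adjusted p = 0.252 for ER chaperones (19 tested, median -0.12), 0.466 for antioxidant genes (25, -0.01), 0.623 for p53 targets (20, 0.15), and 0.787 for apoptosis regulators (20, 0.00). Small RNA pathway genes had 0.301 (13, -0.07), cytokines and NF-kB targets 0.307 (16, -0.08), immediate early genes 0.722 (28, 0.07) and fatty acid synthesis 0.749 (17, 0.00). The non-coding RNA list, fixed for RNA quality and depletion, had 0.0928 (12, 0.18), and neural markers 0.913 (5, 0.08). The non-coding list had no match for Rn18s or Rn45s, so it does not measure depletion of cytosolic ribosomal RNA. Over all genes the members past the threshold were Taldo1 among antioxidant genes, Plk3 among p53 targets, and the cytokine Ccl2 (0.497 times, edgeR adjusted p = 0.0488) and the AP-1 subunit Fosl1 (0.510 times, edgeR adjusted p = 0.04), which both fell. Adjusted over the list alone, 1 antioxidant gene rose, 1 p53 target fell, 2 cytokine genes fell, 1 immediate early gene rose and 3 fell, 1 fatty acid synthesis gene rose, 1 non-coding RNA rose, and 0 passed in the other 4 lists. The antioxidant and fatty acid synthesis tests pointed up although their medians were at or just below 0, and the immediate early test pointed down with a positive median. Immediate early genes were called lower within replicates 1 and 2 (median -0.05, adjusted p = 0.0391). They were also called lower without the block when Cox7a2l siRNA replicate 3 was left out (median -0.41, adjusted p = 9.7e-05). That fit keeps replicate 3 in the control group only. These genes were higher in replicate 3 of both groups (median log2 difference 0.64 and 0.95), so this call is no further support. With the block and pair 2 left out, p53 targets were called higher (median 0.34, adjusted p = 0.033). Markers of adipocytes, bone and cartilage, immune cells, and endothelium and epithelium had 3, 4, 2 and 3 tested members, too few for a list test, and 0 passed over all genes. Adjusted over the list alone, 1 endothelial or epithelial marker rose and 1 fell, and 0 did in the other 3.

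**Figure D3:**
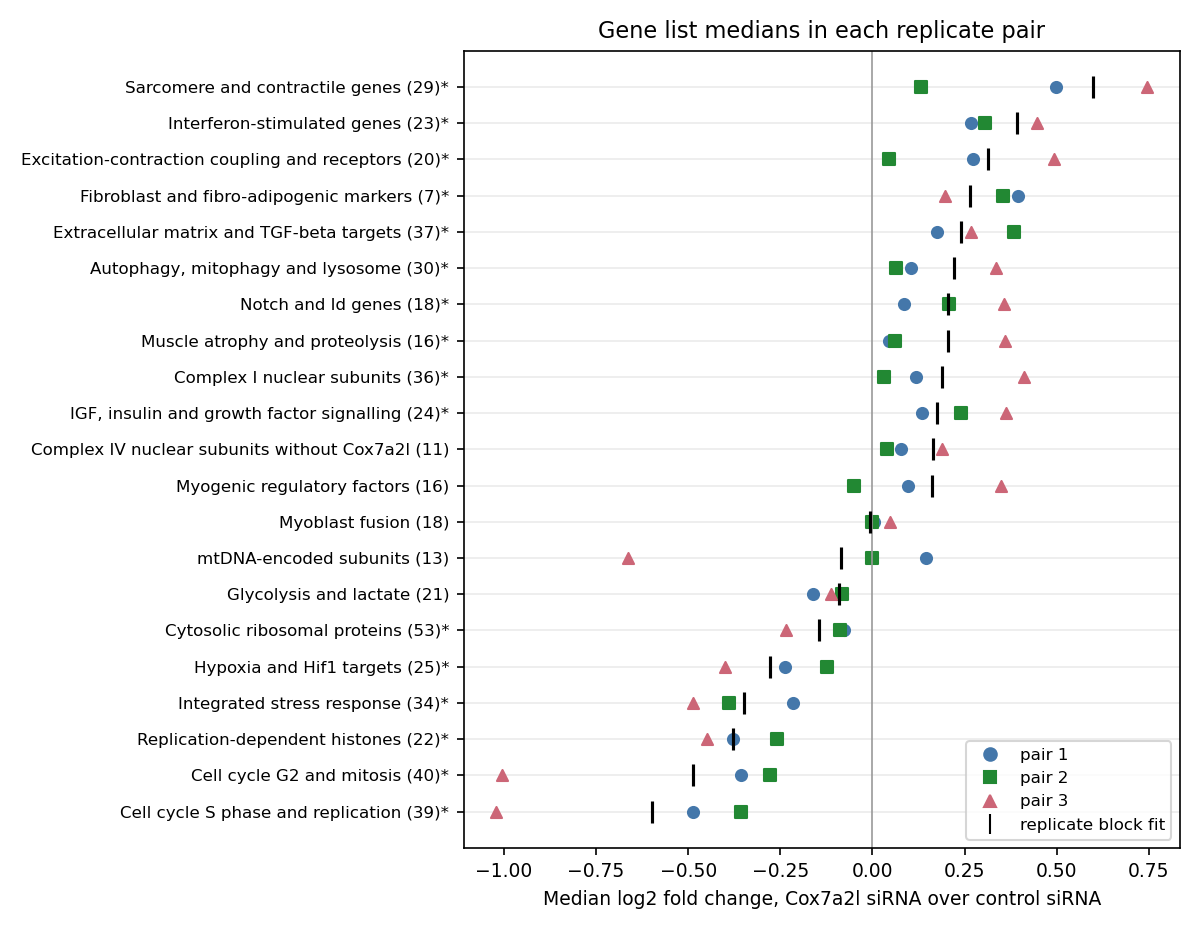
Median log2 fold change (Cox7a2l siRNA over control siRNA) of gene lists in each replicate pair, with circles, squares and triangles for pairs 1, 2 and 3, black ticks for the median in the fit with the replicate block, and the number of tested genes in brackets; an asterisk marks camera adjusted p under 0.05 with the block at a preset correlation. The medians of S phase (-0.49, -0.36 and -1.02) and of G2 and mitosis (-0.36, -0.28 and -1.0) lie below 0 in each pair, and those of the sarcomere list (0.50, 0.13 and 0.75) above 0.

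The authors' deposited table lists 808 genes at adjusted p below 0.05, 368 higher and 440 lower, of which 625 have an absolute log2 fold change of at least 0.5 (293 higher, 332 lower). In the authors' deposited table Cox7a2l has a log2 fold change of -3.45, with a standard error of 0.20 and adjusted p = 1.1e-60 by DESeq2. Of those 808 genes, 107 were also called in the same direction by edgeR with the replicate block and 2 without it. Across the 15022 genes, which are not independent replicates, log2 fold changes correlated with those of the authors' deposited table at r = 0.969 with the block and 0.939 without it. Both analyses use the same counts, so the overlap is not independent evidence.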

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

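The term for replicate 3, the fits without replicate 3, the alternatives of the blocked fit and the blocked list tests were chosen only after the data were seen. Cox7a2l kept its direction under every alternative, at -3.61 to -3.22 when 1 library was left out. For each value below that changed, the cause was not tested unless it is named. Depth limits low genes most in Cox7a2l siRNA replicate 3.

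Without the block 2 genes passed, and 0 to 2 when 1 library was left out (0 to 2 lower). DESeq2 called 40 (23 higher, 17 lower), the replicate block 109 (65 higher, 44 lower) and the term for replicate 3 197 (118 higher, 79 lower). TPM over genes with a mean of at least 1, and the fit without both replicate 3 libraries, each gave 1 gene higher. With the replicate block DESeq2 gave 507 (232 higher, 275 lower), library size alone 58 (41 and 17), no filter 1257 (568 and 689), no robust step 63 (18 lower), and TPM 12 (5 and 7). Leaving out 1 pair gave 51 to 1210 genes (31 to 542 higher, 20 to 668 lower). Of the 109, 91 were also called with voom, 105 with DESeq2, 95 with the stricter filter and 5 on TPM.

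Gene lists called without the block were 5 higher and 6 lower. The replicate block called 10 higher, the term for replicate 3 9, and leaving out 1 library 1 to 9. With the block and pair 1, 2 or 3 left out, 10, 11 and 8 were higher. With an estimated correlation or fry, 0 were higher and 0 lower, with the block or without it. Only the p-values differ in those tests, so the medians stay at 0.19 for complex I, -0.36 for the integrated stress response, 0.62 for the sarcomere, -0.58 for S phase and -0.50 for G2 and mitosis without the block, and at 0.19, -0.35, 0.60, -0.60 and -0.49 with it. For these 5 lists fry gave adjusted p = 0.316 to 0.762 without the block and 0.198 to 0.365 with it. Over the 6 libraries the replicate block changed no call other than those given beside each result.

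The direction of a list is that of the camera test, so its median can have the other sign. Without both replicate 3 libraries complex I (0.085) and autophagy (0.11) were no longer called, and glycolysis (-0.085) was among the lists gained. The direction turned there for mtDNA-encoded subunits (0.20), myogenic factors (0.068) and p53 targets (0.011). With the block, leaving out pair 1 called mtDNA-encoded subunits lower (-0.26) and turned immediate early genes (0.091). Leaving out pair 2 called complex IV (0.20) and turned antioxidant genes (-0.068), the mixed list of CDK inhibitors and D-type cyclins (-0.040), immediate early genes (0.12), cholesterol synthesis (0.0033), fatty acid synthesis (-0.066) and neural markers (-0.059). Leaving out pair 3 turned mtDNA-encoded subunits (0.20), myogenic factors (0.055) and p53 target genes (-0.0074). On TPM complex I (-0.085) and autophagy (-0.086) were no longer called, and mtDNA-encoded subunits (-0.35), fatty acid synthesis (-0.25) and mitochondrial ribosomal proteins (-0.19) turned.

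Genes that turned without passing were Mymk (-0.81 with voom, -0.035 with the replicate block, -0.31 and -0.62 on TPM with 1 and 0.1 added, -0.69 without both replicate 3 libraries) and Myod1 (-0.0083 on library size, -0.23 and -0.24 on TPM, -0.084 without both replicate 3 libraries). On library size and on log2(TPM + 1), the medians of all genes were -0.03 and -0.18. Leaving out single libraries without the block gave these ranges: Myh3 -1.95 to 4.15, Mymk -2.75 to 2.49, Myog -2.06 to 4.06, Cdkn1a -0.15 to 0.80, Myod1 -0.11 to 0.13, Tnnt1 -0.15 to 4.19, Actc1 -1.86 to 4.78 and Heyl -1.05 to 4.50. Genes that kept their sign but moved by over 1.5 times were Dcn (0.33 to 3.16), Plxdc2 (1.25 to 2.74), Acta2 (0.69 to 1.33), Fbxo32 (0.57 to 1.24), Psat1 (-0.98 to -0.46), Ccl2 (-1.57 to -0.42), Fosl1 (-1.21 to -0.66), Mki67 (-1.01 to -0.54) and Cox7a2 (-0.36 to -0.034). For list medians the ranges were complex I 0.095 to 0.27, mtDNA-encoded subunits -1.75 to 1.66, TCA cycle -0.10 to 0.030, glycolysis and lactate -0.22 to 0.0097, antioxidant genes -0.076 to 0.045, myogenic factors -0.18 to 0.32, sarcomere -0.58 to 1.64, and excitation-contraction coupling -0.18 to 0.61. Fatty acid oxidation ran from -0.022 to 0.089, myoblast fusion from -0.17 to 0.17, p53 targets from 0.029 to 0.30, apoptosis regulators from -0.084 to 0.038, immediate early genes from -0.41 to 0.30, and neural markers from -0.36 to 0.32. Fatty acid synthesis and SREBP1 targets ran from -0.065 to 0.12. Leaving out Cox7a2l siRNA replicate 3 keeps replicate 3 in the control group only, and the lowest values of the muscle genes come from there. Called lists that kept their sign but moved by over 1.5 times were Extracellular matrix and TGF-beta targets (0.13 to 0.36), Autophagy, mitophagy and lysosome (0.094 to 0.28), Replication-dependent histones (-0.60 to -0.092), Hypoxia and Hif1 targets (-0.34 to -0.16), Cytosolic ribosomal proteins (-0.19 to -0.082), Integrated stress response (-0.47 to -0.19), Cell cycle S phase and replication (-0.73 to -0.38), Interferon-stimulated genes (0.20 to 0.50), Notch and Id genes (0.076 to 0.28), IGF, insulin and growth factor signalling (0.069 to 0.33), Muscle atrophy and proteolysis (0.10 to 0.29) and Fibroblast and fibro-adipogenic markers (0.15 to 0.33). Of all alternatives tried for the main results of the comparison, 235 kept direction and call, 61 moved, 30 no longer passed, 5 came to pass and 14 turned. For the other genes and lists these were 1264 kept, 39 no longer passed, 134 came to pass and 48 turned.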

Other observations

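Of the tests below, 4 were chosen only after the result they weigh was seen. These were the model behind the authors' deposited table, the medians of pairs 1 and 2, and the splits for the replicate block and for the replicate 3 term. The replicate 3 libraries of both groups differed from replicates 1 and 2 in several lists of muscle genes. The median log2 difference of 29 sarcomere genes, replicate 3 over replicates 1 and 2 with 0.5 CPM added, was 1.53 in the control group and 2.10 in the Cox7a2l siRNA group, and that of 20 genes of excitation-contraction coupling 0.62 and 1.16. It was 0.52 and 0.56 for 16 myogenic regulatory factors and 0.32 and 0.41 for 18 myoblast fusion genes. In the order of replicates 1, 2 and 3, Tnnt1 had 1.78, 1.17 and 15.9 CPM in the control group and 8.18, 3.30 and 71.1 CPM after Cox7a2l siRNA, Mymk 1.85, 2.41 and 21.9 CPM and 2.03, 0.562 and 34.1 CPM, and Heyl 2.11, 1.72 and 29.4 CPM and 7.42, 3.44 and 121.8 CPM. The 28 immediate early genes had medians of 0.64 and 0.95, and the 22 replication histones -0.64 and -0.83. Genes of S phase differed by -0.10 in the control group and -0.74 after Cox7a2l siRNA, and those of G2 and mitosis by 0.09 and -0.65. Each value compares 1 library with 2, and the difference between the groups was not tested.

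The fold changes of replicates 1 and 2 came back in the replicate 3 pair, which shares no library with them. Of the 200 genes with the smallest p in replicates 1 and 2, 196 (98.0%) had the same sign in the replicate 3 pair. Genes are not independent replicates and the signs come from 1 pair of libraries, so no interval is given. Across 12757 genes with a mean of at least 2 CPM the log2 fold changes of the separate sets correlated at r = 0.462. This may be a shared effect of the Cox7a2l siRNA in both sets of libraries, though an effect of its sequence on other transcripts would recur in the same way, and the study holds 1 siRNA.

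Acta2 and other actin-binding genes among those higher with the replicate block prompted a hypothesis that smooth muscle type actin and myosin genes rise as a class. It was tested, in the same libraries, on 14 further genes assigned to that class whose values had not been looked at. Of these, 12 were tested, with a median log2 fold change of 0.41 and pair medians of 0.30, 0.29 and 0.53, and 10 were positive. The 12 held the myosin light chain Myl6 and no actin. Most of the others bind actin or sit at adhesions, among them Vcl, Zyx and Smtn. A rise of actin and myosin genes themselves was therefore not tested. Camera with the replicate block gave p = 2.0e-04 at the preset correlation, and p = 0.159 with an estimated correlation, and fry gave p = 0.0604. Single members did not pass over all genes, and those nearest were Csrp1 (log2 fold change 0.64, standard error 0.13, edgeR adjusted p = 0.0576) and Pdlim7 (0.53, standard error 0.14, edgeR adjusted p = 0.0937), while Smtn and Tns1 were at -0.27 and -0.35. A rise of these 12 genes as a set may be present, and it rests on the preset correlation.

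Gm6969 fell with Cox7a2l. Reads shared with Cox7a2l transcripts could account for this, since 78.2% of the 31-base words in the Gm6969 transcript also occur in Cox7a2l. The only other gene in the reference with such words was Gm10242, with 1.33% of its words. How far Gm6969 is transcribed on its own stays open.

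The replicate 3 libraries stand apart, where the median of the 13 single messages of mitochondrial DNA was 10.3-fold that of replicates 1 and 2 in the control group and 6.88-fold in the Cox7a2l siRNA group, and their summed share of the counts 2.78% and 1.61% against 0.589% to 0.616%. A trend with GC content, transcript length and expression level is argued against as the whole cause, since it explained at most 2.97% of the variance across genes, and the mitochondrial messages kept a median excess of at least 2.89 (log2) once it was removed. A model with a term for replicate 3 matched the authors' deposited log2 fold changes to within 1.3e-09. That match shows which model gives their values, and cannot tell why the replicate 3 libraries differ. A batch may lie behind the difference, and was not tested otherwise. The mean fragment length implied by the ratio of counts to TPM was 166 bases in control replicate 3 and 177 to 181 in the other 5 libraries. Whether such a batch would be one of library preparation or of cells at another density or stage of differentiation stays open, and no biological explanation was tested.

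Cell cycle lists were lower and the contractile list higher after Cox7a2l siRNA. A trend with GC content, transcript length and expression level is argued against, since 0 of 10000 random lists matched on these properties lay as far out as any of the 3 lists. For the cell cycle lists, the depth or quality of the replicate 3 pair, whose Cox7a2l siRNA library was the smallest, is argued against as the whole cause. Their medians in pairs 1 and 2 were at most -0.28. The contractile list had medians of 0.50 and 0.13 in those pairs, so the argument is weaker for it. An off-target action of the siRNA, a difference in cell density between dishes and an effect of losing Cox7a2l stay open as untested, and the call itself holds only with a preset correlation.

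Other splits of the 6 libraries were too few for a share under 0.05 in each design. Of the 10 splits into 3 and 3, the real one gave 2 genes without the block and the highest other gave 0. Of the 4 splits that part every pair, the real one gave 109 with the replicate block and the highest other 0. Of the 6 that part the replicate 3 libraries, the real one gave 197 with the term for replicate 3 and the highest other 0.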
